A study of Medicago truncatula with 8 samples.

How the data were processed

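RNA sequencing libraries were made from polyadenylated RNA of Medicago truncatula hairy roots that express a tagged RPL18 protein, either from total cellular RNA or from RNA obtained by translating ribosome affinity purification (TRAP), 48 h after inoculation with Sinorhizobium meliloti or water. The 8 libraries form 4 groups of 2 biological replicates per the labels. The labels do not state whether libraries with the same replicate number come from the same plants or day, so the replicate number was not a term of the model.

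The deposited table holds FPKM (fragments per kilobase of transcript, scaled to each library's mapped fragments) per the file headers, 1 column per library. Per the submitters' processing notes, TopHat2 and Cufflinks were used. Their versions and parameters, the genome build and the annotation are not given in the sources used here, nor is any filter on the loci. Loci carry Cufflinks identifiers, chromosome coordinates, a gene identifier where there is one, and a description. The library totals differ, so the values were not rescaled to a fixed sum, and a locus of 101 bp accounts for most of that difference; its highest FPKM times its length implies more fragments than a library holds, so FPKM of very short loci are estimates that can fail. Counts were not used here, hence the depth per library is unknown and no interval or detection limit was computed from it. An exact 0 is given as listed at 0. All per-sample columns were used.

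FPKM were transformed to log2(FPKM + 1), and loci with a mean of at least 1 FPKM over the 8 libraries were tested, 19726 of 29995. This pseudocount makes differences of loci near 1 FPKM smaller than their ratio of FPKM. A linear model of the 4 group means was fitted in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with an intensity trend), and p values were adjusted by Benjamini-Hochberg, with a threshold of 0.05 and no minimum fold change. All 8 libraries share 1 estimate of the spread because each group has 2 libraries. The contrasts were inoculated against mock in Total RNA, the same in TRAP RNA, the difference of these responses (the interaction), and TRAP against Total RNA averaged over both treatments. Tests are two-sided by construction in limma. SE is the moderated standard error of the contrast. A count test was not used because the deposited values are not counts.

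Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 23 lists and 4 contrasts, 92 tests, of which 14 were called; with an estimated correlation 0 were called. The lists by identifier were early nodulation genes, symbiotic signalling pathway, late nodule genes and reference genes. Lists by keyword in the table's descriptions covered nodulins, NCR and leghemoglobin, cytosolic ribosomal proteins, translation factors and flavonoid biosynthesis. They also covered ethylene, cytokinin, auxin, gibberellin, defence, peroxidases and Rboh, cell cycle and histones, cell wall remodelling, nitrate and nitrogen, and photosynthesis. The others were vascular and endodermis markers, root hair and epidermis markers, RNA silencing and decay, NF-Y with GRAS and ARF transcription factors, heat shock and stress, transposable elements and hypothetical proteins. Lists with fewer than 5 tested members were not given to camera. CLE12, LYK3, EIN2, CNGC15a and EF1a are not in the table under the identifiers listed, and ACT2 was left out because the table describes that locus as another kind of gene. Loci without a gene identifier stood in for non-coding transcripts, which the table does not tell apart.

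The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the RPL18 genes first. For each comparison it takes the 10 largest rises and 10 largest falls among loci past the threshold whose groups do not overlap, preferring loci with a description. Where fewer than 5 pass in a direction, it takes the 5 with the smallest unadjusted p. It adds the genes of the identifier lists and up to 4 members with the smallest p of each keyword list described. Medtr8g014470 in TRAP against Total RNA, and Medtr4g065990, Medtr7g074730, Medtr3g415650, XLOC_006750 and XLOC_012727, and genes named for the other families and neighbours, were chosen after their values were seen.

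Alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 FPKM, median-ratio size factors computed on FPKM, quantile normalization, eBayes without trend or with robust fitting, a minimum log2 change of 1, the replicate number as a block, the spread from the 4 compared libraries alone, and leaving out each library in turn. Omitting loci under 300 bp was added after seeing the data. The model was tested on simulated data of the same size with 50 loci changed per fold. The simulated noise was independent between libraries. In the data, differences between replicates 1 and 2 correlated between groups, so the shares recovered need not hold for the data. In the Total comparison it recovered 0% of 2-fold, 52% of 4-fold, 88% of 8-fold and 100% of 16-fold changes. The same shares were 0%, 52%, 92% and 98% in the TRAP comparison, 0%, 6%, 66% and 76% for the interaction, and 8%, 90%, 100% and 100% for TRAP against Total. Unchanged loci called in these runs numbered 8, 8, 3 and 7.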

Results

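Gene expression was measured in hairy roots of Medicago truncatula, a model legume, that had been transformed by Agrobacterium rhizogenes with a construct driving an epitope-tagged ribosomal protein L18 from the 35S promoter. Roots received 10 ml of a suspension of Sinorhizobium meliloti, the bacterial partner in the nitrogen-fixing nodule symbiosis, or 10 ml of water (mock), and were collected at 48 h after inoculation. From each treatment, polyadenylated RNA was sequenced from total cellular RNA (Total) and from RNA recovered with the tagged ribosomes by translating ribosome affinity purification (TRAP). The 4 groups, Total mock, Total inoculated, TRAP mock and TRAP inoculated, hold 2 biological replicates each, 8 libraries in all.

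The deposited table lists FPKM for 29995 loci, of which 28627 carry a Medtr gene identifier and 1368 carry none. FPKM gives no counts, so the read depth of each library is unknown. Loci above 0 numbered 26292 to 27292 in the Total libraries and 23201 to 24684 in the TRAP libraries. A single locus of 101 bp without a gene identifier, XLOC_006750 (chromosome 1, 23320890 to 23320990), reached 40200000 FPKM, was listed at 0 in 2 libraries and took most of the FPKM total of the other 6. Without it, library totals ran from 692458 to 1042280 FPKM. The 100 highest loci held 17.1% to 21.0% of each Total library and 22.9% to 27.4% of each TRAP library. Coordinates are those of the table, whose genome build is not given in the sources used here.

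Inoculated and mock Total RNA were compared to ask which transcripts change in abundance at this early stage of the symbiosis. The largest rise among loci past the threshold was that of ENOD11 (Medtr3g415670, chromosome 3, 4571409 to 4572174), an early nodulin gene widely used as a marker of Nod factor response and infection. It went from 0.669 and 0.210 FPKM in the mock replicates to 77.3 and 62.8 FPKM in the inoculated ones, a ratio of group means of 159. On the log2(FPKM + 1) scale the rise was 5.64 ± 0.32 (SE, n = 2 per group; limma, Benjamini-Hochberg adjusted p = 0.00385). A lipid transfer protein gene, Medtr5g011960 (chromosome 5, 3530924 to 3532024), rose from 1.15 and 0.123 FPKM to 55.3 and 38.2 FPKM (log2 difference 4.92 ± 0.38 SE, adjusted p = 0.0138).

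In limma, 8 of the 19726 loci tested were higher after inoculation and 0 were lower. At an unadjusted p under 0.05 there were 94 loci, 83 of them higher, against 986 that a uniform distribution of p gives. With fewer small p than that, the count of 8 need not give the size of the response. Medtr3g081140 (chromosome 3, 36751135 to 36752470) is annotated as a cysteine-rich TM module stress tolerance protein. It was listed at 0 in both mock libraries and stood at 20.5 and 19.95 FPKM after inoculation (log2 difference 4.41 ± 0.31 SE, adjusted p = 0.00916). Medtr5g045470, an inhibitor of trypsin and hageman factor-like protein, rose by 4.10 ± 0.41 (SE, adjusted p = 0.0310), to 24.4 and 21.2 FPKM. Medtr4g117000 (chromosome 4, 48460105 to 48461676), a glycoside hydrolase family 18 protein of the chitinase type, rose by 3.74 ± 0.35 (SE, adjusted p = 0.0244), to 17.97 and 9.08 FPKM. The hypothetical protein gene Medtr4g088510 rose by 3.92 ± 0.35 (SE, adjusted p = 0.0233), and the putative transmembrane protein gene Medtr6g022560 by 3.48 ± 0.29 (SE, adjusted p = 0.0176). The last of the 8, Medtr1g083710 (chromosome 1, 37259540 to 37259760), is a hypothetical protein locus of 221 bp. It was listed at 0 in both mock libraries and at 7.09 and 11.1 FPKM after inoculation (adjusted p = 0.0233). A value of 0 at so short a locus can be a failed FPKM estimate, so this rise is uncertain.

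**Figure D1:**
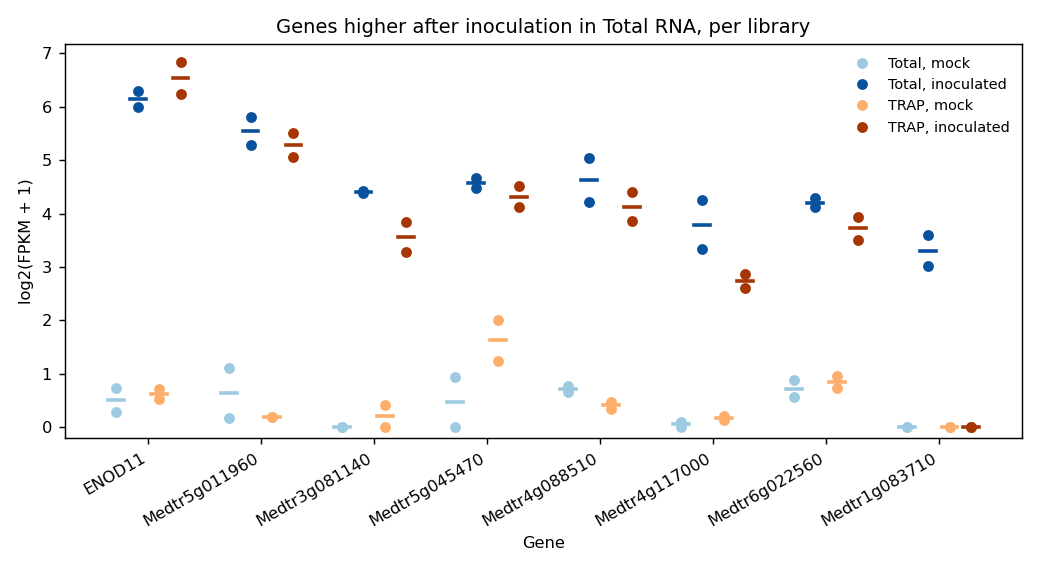
Expression of the 8 genes past the threshold in Total RNA, as log2(FPKM + 1) per library (dots) with the group mean (dash), in the 4 groups of 2 libraries. ENOD11 lies between 62.8 and 113 FPKM in the 4 inoculated libraries and at 0.669 FPKM or below in the 4 mock ones; Medtr1g083710 is at 0 in every TRAP library.

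Of 21 early nodulation genes in the table, 16 passed the level filter. Of these 1, ENOD11, passed over all genes tested and 7 passed when adjusted over the list alone. Those 7 were ENOD11, NPL, CBS1, VPY, NF-YA1, PUB1 and LBD16, all higher after inoculation. In all, 14 of the 16 had a positive log2 difference, with a median of 0.81. NPL (Medtr3g086320), a pectate lyase that loosens the wall at infection sites, went from 0.0175 and 0 FPKM to 9.16 and 4.67 FPKM (log2 difference 2.91 ± 0.44 SE, adjusted p over the list 0.00149). NF-YA1 (Medtr1g056530), a CCAAT-binding transcription factor of infection and nodule development, went from 0.152 and 0.963 FPKM to 5.33 and 3.44 FPKM (1.82 ± 0.39 SE, adjusted p over the list 0.00519). VPY, the ankyrin repeat protein vapyrin needed for infection threads, had a log2 difference of 1.51 ± 0.29 SE, and CBS1 one of 2.18 ± 0.34 SE. Limma's camera ranked the list above the other genes (adjusted p = 7.67e-44 with the preset correlation of 0.01), a call lost with an estimated correlation (adjusted p = 0.320 with an estimated correlation). The master regulator NIN (Medtr5g099060) lay below the filter, at 0.282 and 0.327 FPKM in mock and 2.94 and 1.37 FPKM in inoculated Total RNA.

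The symbiotic signalling list, with the Nod factor receptor NFP and the kinases DMI2 and DMI3 among its 15 tested members, had 0 past the threshold in limma in Total or TRAP RNA, over all genes or adjusted over the list alone, and 0 with an unadjusted p under 0.05. DMI2 stood at 49.3 and 30.7 FPKM in mock and 47.5 and 36.3 FPKM in inoculated Total RNA. Genes of mature nodules were near the floor: the leghemoglobin genes LB1 and LB2, SYMCRK and DNF2 did not exceed 0.646 FPKM in any library. The only late nodule gene tested, DNF1, had log2 differences of -0.07 in Total and 0.13 in TRAP RNA.

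Among the keyword lists, 3 were lower in Total RNA after inoculation by camera, and 0 of their members passed in limma or had an unadjusted p under 0.05. The photosynthesis list, a marker of green or light-exposed tissue, had 58 of 70 members negative with a median of -0.15 (adjusted p = 0.00371, and adjusted p = 0.998 with an estimated correlation). Its members with the smallest p carry the names of plastid-encoded proteins, Q(B) protein Medtr4g051290 and the CP43 apoprotein Medtr8g014470, with log2 differences of -1.82 ± 1.16 and -0.68 ± 0.44 (SE). The gibberellin list had 30 of 37 members negative (adjusted p = 0.0162, and adjusted p = 0.998 with an estimated correlation), with gibberellin 2-beta-dioxygenase Medtr1g011580 at -0.65 ± 0.31. The heat shock and stress list of 247 members had a median of -0.09 (adjusted p = 0.0310, and adjusted p = 0.998 with an estimated correlation). Some members passed only when adjusted over the list alone. They were the early nodulin-12A gene Medtr3g415650 among the nodulins (log2 difference 3.29 ± 0.56 SE), the dihydroflavonol 4-reductase-like gene Medtr7g074730 among the flavonoid genes (2.65 ± 0.42), and NPL among the cell wall genes. In Total RNA camera called no other list on the deposited scale, though the nitrate and nitrogen list, with 34 of 44 members negative, came near (adjusted p = 0.0533, and 0.0455 under quantile normalization). Outside the hypothetical proteins (2 higher) and ENOD11 no list member passed over all genes.

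None of the 5 falls with the smallest p passed; the cytochrome P450 gene Medtr5g094550 had a log2 difference of -1.07 ± 0.42 (SE, adjusted p = 1) and the unannotated locus XLOC_048876 one of -1.55 ± 0.28 (SE, adjusted p = 0.657). Of the 8 loci, 2 still passed without Total mock replicate 1 (beside 1 lower call), 0 without Total mock replicate 2, 0 without Total inoculated replicate 1 (beside 1 other call), 0 without Total inoculated replicate 2, and 4 without either TRAP mock replicate. The count was 5 with a pseudocount of 0.1 and 0 when the spread came from the 4 Total libraries alone, where 131 loci had an unadjusted p under 0.05.

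The same comparison in TRAP RNA asked which transcripts change on ribosomes. ENOD11 again rose most among the loci that passed, from 0.630 and 0.432 FPKM to 113 and 74.4 FPKM, a ratio of group means of 177 (log2 difference 5.92 ± 0.32 SE, n = 2 per group; limma, Benjamini-Hochberg adjusted p = 0.00266). The lipid transfer protein gene Medtr5g011960 rose from 0.134 and 0.143 FPKM to 44.5 and 32.4 FPKM (5.10 ± 0.38 SE, adjusted p = 0.0159). Medtr3g081140 rose by 3.35 ± 0.31 and Medtr4g088510 by 3.72 ± 0.35 (SE, adjusted p = 0.0435 for each).

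These 4 loci were all that passed in TRAP RNA in this model: 4 higher and 0 lower in limma. With the replicate number as a block, 7 were higher and 2 lower. Without the block 258 loci had an unadjusted p under 0.05, 111 of them higher, against 986 that a uniform distribution of p gives. All 4 were among the 8 loci called in Total RNA. The other 4 loci called in Total RNA did not pass here. Medtr6g022560 had a log2 difference of 2.88 (adjusted p = 0.0549), Medtr4g117000 one of 2.56 (adjusted p = 0.263), Medtr5g045470 one of 2.69 (adjusted p = 0.447), and Medtr1g083710 was listed at 0 in all 4 TRAP libraries. A wound-induced-like protein gene, Medtr3g031270, stood at 0.570 and 0.260 FPKM in mock and 32.8 and 14.5 FPKM in inoculated TRAP RNA (4.03 ± 0.51 SE, adjusted p = 0.192). The caffeic acid O-methyltransferase gene Medtr1g096310 stood at 17.7 and 11.2 FPKM in mock and 90.0 and 67.3 FPKM in inoculated TRAP RNA (2.38 ± 0.37 SE, adjusted p = 0.483). The falls with the smallest p did not pass. Medtr8g031990, an NAD(P)-binding rossmann-fold protein gene, was at 21.2 and 11.8 FPKM in mock and listed at 0 after inoculation (adjusted p = 0.199). With the replicate number as a block it passed as a fall, as did XLOC_051136. Medtr6g022560, Medtr3g031270 and Medtr1g096310 then passed as rises. XLOC_051136 (scaffold0916, 2833 to 3062) spans under 300 bp and was listed at 0 in both inoculated TRAP libraries. A failed FPKM estimate is not excluded for that locus. The hypothetical protein gene Medtr6g090460 had a log2 difference of -1.59 ± 0.32 (SE, adjusted p = 1).

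Of the 16 early nodulation genes tested, 1 passed over all genes in TRAP RNA and 6 passed when adjusted over the list alone: ENOD11, NPL, NF-YA1, PUB1, VPY and LBD16, all higher. NPL had a log2 difference of 2.67 ± 0.44 and NF-YA1 one of 1.97 ± 0.39 (SE), and 12 of the 16 differences were positive, with a median of 0.84. Camera ranked the list above the other genes (adjusted p = 3.39e-16, and adjusted p = 0.926 with an estimated correlation). The response was larger in replicate 1, with a list median of 1.29 in Total and 1.02 in TRAP RNA, than in replicate 2, with 0.41 and 0.52.

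**Figure D2:**
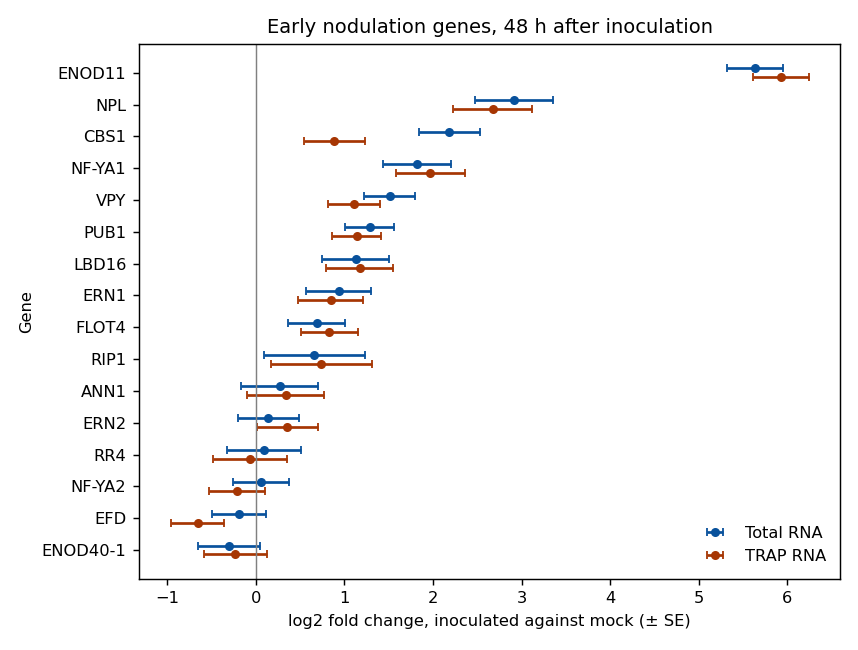
Log2 difference of inoculated and mock roots for the 16 early nodulation genes tested, in Total and TRAP RNA, with bars of 1 SE from limma (2 libraries per group). ENOD11 is at 5.64 in Total and 5.92 in TRAP RNA; CBS1 is at 2.18 in Total and 0.89 in TRAP RNA.

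The photosynthesis list was also lower in inoculated TRAP RNA, with 61 of 70 members negative and a median of -0.37 (camera adjusted p = 5.01e-05, and adjusted p = 0.998 with an estimated correlation). Here the members with the smallest p were nuclear genes of the rubisco small chain, Medtr7g007120 at -0.85 ± 0.39 and Medtr7g007230 at -0.88 ± 0.49 (SE), neither of which passed. The cytosolic ribosomal protein list had 89 of 102 members positive with a median of 0.14 (camera adjusted p = 0.0366, and adjusted p = 0.998 with an estimated correlation), and 0 members passed in limma or had an unadjusted p under 0.05. In TRAP RNA camera called no other list on the deposited scale, and only ENOD11 and 1 hypothetical protein gene, Medtr4g088510, passed over all genes as list members.

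The count of 4 was 1 or 2 without any of the Total libraries, 1 without TRAP mock replicate 1, 1 higher and 2 lower without TRAP mock replicate 2, and 6 (2 of them among the 4) without TRAP inoculated replicate 2. It was 3 higher and 2 lower with a pseudocount of 0.1 (2 of them among the 4), 2 with a pseudocount of 5 or a filter of 5 FPKM, 1 with no filter, and 0 when the spread came from the 4 TRAP libraries alone, where 166 loci had an unadjusted p under 0.05.

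The responses of TRAP and Total RNA were then set against each other to ask whether inoculation moved transcripts on or off ribosomes beyond their change in abundance. For ENOD11 the TRAP response exceeded the Total response by 0.29 ± 0.45 on the log2 scale (SE), and for Medtr5g011960 the difference was 0.18, both within their error. CBS1, a gene of infection threads with a CBS domain, had a Total response of 2.18 and a TRAP response of 0.89, a difference of -1.30 ± 0.49 (SE, limma, Benjamini-Hochberg adjusted p = 1). Medtr1g083710, which rose in Total RNA and was listed at 0 in TRAP RNA, had the smallest p for the difference, at -3.30 ± 0.43, and Medtr8g031990 had -3.46 ± 0.75 (SE, adjusted p = 1 for each).

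In limma 0 of the 19726 loci passed for this difference, with 53 at an unadjusted p under 0.05 against 986 that a uniform distribution of p gives. The DUF3511 domain protein gene Medtr8g018360 had a positive difference of 1.44 ± 0.39 and the hypothetical protein gene Medtr2g084420 one of 2.24 ± 0.65 (SE, adjusted p = 1 for each). The ribosomal protein list had 91 of 102 members with a higher response in TRAP than in Total RNA, with a median difference of 0.18 (camera adjusted p = 0.0366, and adjusted p = 0.998 with an estimated correlation). The flavonoid biosynthesis list had 52 of 75 positive with a median of 0.16 (camera adjusted p = 0.00863, and adjusted p = 0.998 with an estimated correlation). Its 2 members with the smallest p were chalcone and stilbene synthase genes, which act at the entry to the flavonoid pathway. Of these, Medtr5g007730 averaged 45.3 FPKM in mock and 29.1 FPKM in inoculated Total RNA, and 11.8 and 27.9 FPKM in TRAP RNA (difference 1.56 ± 0.75 SE, adjusted p = 1). Camera called no other list on the deposited scale, and 0 list members passed, over all genes or adjusted over the list alone. Across the 19726 loci, which are not independent replicates, the responses in Total and TRAP RNA had a Pearson r of 0.27 and a Spearman rho of 0.35. In replicate 1 r was 0.31 and rho 0.25, and in replicate 2 r was 0.05 and rho 0.23. The 101 bp locus XLOC_006750 is among these loci and weighs on r. In replicate 2 it went from 0 to 40200000 FPKM in Total and from 7430000 FPKM to 0 in TRAP RNA. The count of 0 was 1 without TRAP inoculated replicate 1 and 2 without TRAP inoculated replicate 2.

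TRAP and Total RNA were compared over both treatments to ask which transcripts are over- or under-represented on tagged ribosomes. The largest rise among loci past the threshold was that of an RPL18 gene itself, Medtr1g083460 (60S ribosomal protein L18-3, chromosome 1, 37145693 to 37147930). It averaged 860 and 732 FPKM in mock and inoculated Total RNA and 10325 and 10136 FPKM in TRAP RNA. In limma, with the 4 libraries per RNA type taken as independent, the log2 difference was 4.01 ± 0.78 (SE, Benjamini-Hochberg adjusted p = 0.0157). The other 60S L18 genes, Medtr7g108805 and Medtr7g112880, had log2 differences of 0.02 ± 0.42 and -0.32 ± 0.38 (SE), neither past the threshold. Their signs turn, to -0.22 under quantile normalization and to 0.14 under median-ratio scaling. The 50S type genes Medtr2g044920 and Medtr4g032660 had 0.41 and -0.12, the latter 0.33 under median-ratio scaling and 0.13 under quantile normalization. Medtr1g083460 varied between replicates. It was 5.07 times higher in replicate 1 than in replicate 2 in Total RNA and 2.15 times in TRAP RNA. TRAP exceeded Total by 10.5 times in replicate 1 and 24.8 times in replicate 2.

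In limma 244 loci were higher and 4586 lower in TRAP RNA, and 8077 had an unadjusted p under 0.05. The model takes the mock and inoculated libraries of each RNA type as independent. Across loci, differences between replicates correlated between mock and inoculated groups, at 0.67 in TRAP RNA and 0.53 in Total RNA. If libraries that share a replicate number are not independent, the SE and p of this comparison can be too small and these counts too high. The median log2 difference of all loci was -0.42 as deposited, -0.03 after median-ratio scaling and 0.03 after quantile normalization. With these scalings the counts became 844 higher and 945 lower, and 816 higher and 837 lower. All 244 higher and 945 of the lower loci were called in the same direction after median-ratio scaling.

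Among the higher transcripts, Medtr1g098680, an ABA/WDS induced protein gene, was at 27.4 to 40.1 FPKM in Total and 96.5 to 133 FPKM in TRAP RNA (log2 difference 1.70 ± 0.22 SE, adjusted p = 0.00853). The ethylene response factor gene Medtr1g074310 rose by 1.89 ± 0.27 (SE, adjusted p = 0.00939), the peptidyl-prolyl isomerase gene Medtr3g117750 by 2.00 ± 0.54 (adjusted p = 0.0348), and the LOB domain gene Medtr5g083010 by 1.75 ± 0.34 (adjusted p = 0.0156). The remaining 5 of the named rises, from 1.46 to 1.73, were a late embryogenesis abundant protein, a monothiol glutaredoxin, a polygalacturonase inhibitor and a pair of putative transmembrane proteins. Among the lower transcripts, the DEAD-box RNA helicase-like gene Medtr1g022305 had a log2 difference of -3.98 ± 0.44 (SE, adjusted p = 0.00736). The AP2 domain transcription factor gene Medtr5g062700 was at 18.3 to 31.3 FPKM in Total and 1.08 to 3.41 FPKM in TRAP RNA, a log2 difference of -3.01 ± 0.33 (SE, adjusted p = 0.00714). The LRR and NB-ARC domain disease resistance gene Medtr3g022300 had -3.37 ± 0.54 (SE, adjusted p = 0.0108), and the 50S ribosomal protein L33 gene Medtr4g051350, whose product belongs to plastid-type ribosomes, had -3.29 ± 0.31 (SE, adjusted p = 0.00641). The named falls also held the myb genes Medtr2g096380 and Medtr4g063100, at -3.27 and -3.04, both larger in replicate 1. In replicate 1 Medtr4g063100 was at 187 and 148 FPKM in Total and 5.56 and 3.09 FPKM in TRAP RNA. In replicate 2 it was at 26.9 and 28.7 FPKM against 14.4 and 11.2 FPKM. Medtr2g096380 was at 135 and 117 FPKM against 3.25 and 3.10 FPKM in replicate 1, and 37.3 and 62.2 FPKM against 15.6 and 14.4 FPKM in replicate 2. Other named genes differed between replicates too. In TRAP RNA Medtr3g022300 was at 0.129 and 0.105 FPKM in replicate 1 and 2.99 and 3.49 FPKM in replicate 2. Medtr1g022305 was at 0.0563 and 0.0626 FPKM, then 0.301 and 1.48 FPKM. The higher Medtr3g117750 was at 236 and 278 FPKM, then 98.4 and 51.2 FPKM.

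Of the 23 lists the photosynthesis list stood highest, with a median of 0.64, which is 1.06 above the median of all loci, and 6 members higher and 3 lower (camera adjusted p = 2.71e-14, and adjusted p = 0.998 with an estimated correlation). Its higher members were nuclear genes such as photosystem I subunit IV A (Medtr1g069235, 1.23 ± 0.25 SE, adjusted p = 0.0163) and Pbs27 (Medtr2g090200, 1.09 ± 0.22 SE, adjusted p = 0.0161). Its lower members carry the names of plastid-encoded proteins: the ycf3 genes Medtr3g035590 and Medtr6g092730 at -1.81 and -1.58, and CP43 Medtr8g014470 at -1.40. The cell cycle and histone list had a median of 0.12 with 2 members higher and 9 lower (camera higher, adjusted p = 3.65e-07, and adjusted p = 0.998 with an estimated correlation). A core histone gene, Medtr4g065990, rose by 0.94 ± 0.23, while the 4 members with the smallest p were cyclin-dependent kinase genes, all lower, with Medtr4g103810 at -1.65. The balance of calls turned with scale, to 10 members higher and 0 lower under median-ratio scaling and 10 higher and 2 lower under quantile normalization. The defence list, with 3 members higher and 11 lower, had a median of -0.22, which is 0.20 above that of all loci (camera higher, adjusted p = 0.0120, and adjusted p = 0.998 with an estimated correlation). Its 3 members with the smallest p were lower, among them WRKY gene Medtr5g044695 at -2.07 and chitinase gene Medtr2g040830 at -1.54. The balance turned to 11 higher and 2 lower under median-ratio scaling and 14 higher and 2 lower under quantile normalization, where camera's call was lost (adjusted p = 0.0674 and 0.156).

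The cytosolic ribosomal protein list had a median of 0.01 and a mean of -0.03, with 1 member, Medtr1g083460, higher and 5 lower (0 lower under median-ratio scaling and 9 under quantile normalization). Camera placed it above the other genes (adjusted p = 0.000229, and adjusted p = 0.998 with an estimated correlation), its median being 0.43 above that of all loci. After quantile normalization its median less that of all loci was -0.24, and it was called lower (adjusted p = 0.00563). Nodulins by annotation were lower, with 28 of 56 members lower and 1 higher (7 and 2 under median-ratio scaling, 5 and 1 under quantile normalization) and a median of -0.85 (camera adjusted p = 0.0209, and adjusted p = 0.998 with an estimated correlation). Of the 56, 33 are described as MtN21/EamA-like transporters, membrane proteins named after a nodulin. They held 23 of the 28 lower members (6 of the 7 under median-ratio scaling), so the list mostly shows this family and not nodulins as a class. Those with the smallest p were of this family, such as Medtr8g041390. It averaged 72.7 and 68.7 FPKM in Total and 20.5 and 14.6 FPKM in TRAP RNA (-1.99 ± 0.31 SE, adjusted p = 0.0101).

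**Figure D3:**
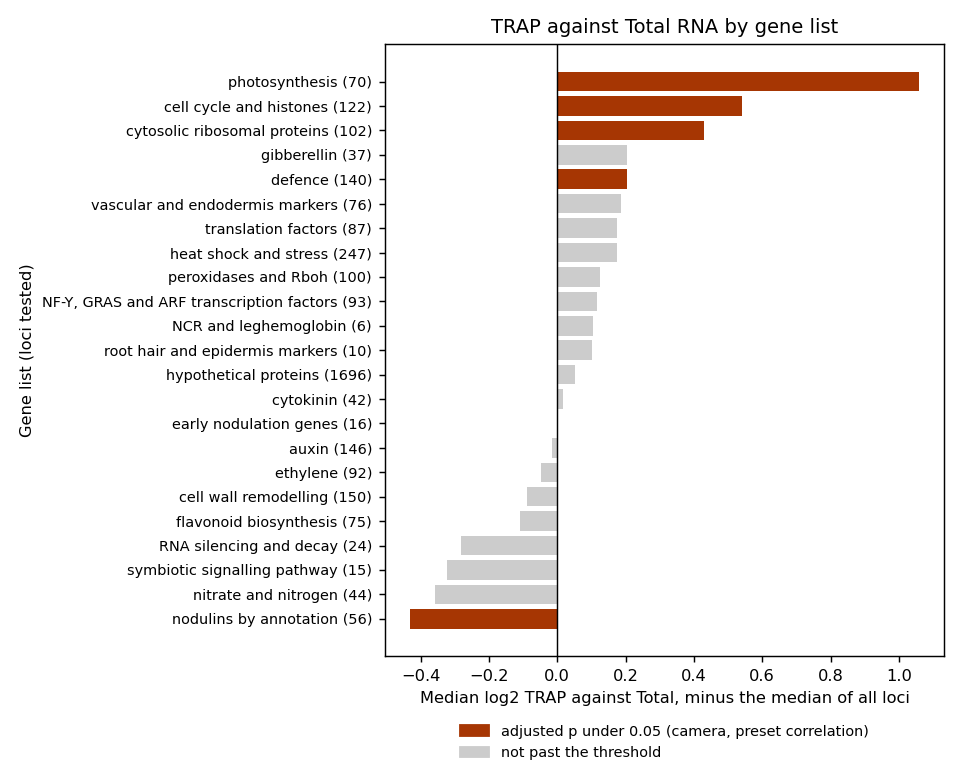
Median log2 difference of TRAP and Total RNA for each of 23 gene lists, minus the median of all loci (-0.42), coloured by the camera call with the preset correlation. Photosynthesis lies 1.06 above and nodulins, of which 33 of 56 are MtN21/EamA-like transporters, 0.43 below all loci. Ribosomal proteins lie 0.43 above, but at -0.24 after quantile normalization.

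Of the 15 symbiotic signalling genes tested, 9 were lower in TRAP RNA over all genes and 10 when adjusted over the list alone. Camera did not call the list on the deposited scale (adjusted p = 0.0705) but called it lower under quantile normalization (adjusted p = 0.0491), and 2 members were lower under that or median-ratio scaling. The lower ones included LIN, an E3 ubiquitin ligase of infection threads, at -1.32 ± 0.25 (adjusted p = 0.0144), the calcium pump gene MCA8 at -1.31 ± 0.21 (adjusted p = 0.0104), the transporter gene LATD at -1.20 ± 0.19 (adjusted p = 0.0105) and NFP at -1.10 ± 0.23 (SE, adjusted p = 0.0192). Among early nodulation genes, NF-YA2 was higher in TRAP RNA by 0.75 ± 0.22 (adjusted p = 0.0463), and RIP1, ENOD40-1 and PUB1 were lower, over all genes and adjusted over the list alone, with 0 of the 3 lower under median-ratio scaling or quantile normalization. The late nodule gene DNF1 was lower, at -0.85 (adjusted p = 0.0278), a call lost under both scalings, and the reference gene UBC9 had -0.88 and did not pass (adjusted p = 0.166).

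On the deposited scale no other list was called by camera, and most of their members past the threshold were lower, as for all loci. The nitrate and nitrogen list (adjusted p = 0.0533) was called lower under median-ratio scaling (adjusted p = 0.0140) and quantile normalization (adjusted p = 0.0107). The counts of higher and lower members were 0 and 15 for translation factors, 2 and 21 for ethylene, 1 and 7 for cytokinin, 2 and 39 for auxin, 0 and 7 for gibberellin, and 0 and 8 for flavonoid biosynthesis. They were 1 and 28 for peroxidases and Rboh, 3 and 38 for cell wall remodelling, 0 and 21 for nitrate and nitrogen, 0 and 11 for RNA silencing and decay, 2 and 14 for NF-Y, GRAS and ARF factors, and 2 and 38 for heat shock and stress. Marker lists of other cell types gave 0 and 12 for vascular tissue and endodermis and 0 and 3 for root hairs and epidermis. NCR peptides and leghemoglobins gave 0 and 2, hypothetical proteins 51 and 367, and the 1 transposable element locus tested did not pass. For several lists this balance did not hold under other scales. Median-ratio scaling and quantile normalization gave 4 and 1, then 2 and 7, for translation factors, 11 and 6, then 13 and 6, for heat shock and stress, and 7 and 4, then 5 and 2, for NF-Y, GRAS and ARF factors. Vascular and endodermis markers gave 1 and 1, then 2 and 0, root hair and epidermis markers 2 and 1 in both, cytokinin 2 and 2, then 3 and 1, and flavonoid biosynthesis 2 and 1, then 1 and 2. Hypothetical proteins gave 119 and 128, then 124 and 85.

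The table does not say which transcripts are non-coding; loci without a gene identifier were examined in their place. Of 707 such loci tested, 0 passed in limma for either response or for their difference. With an unadjusted p under 0.05 there were 5 in Total RNA, 20 in TRAP RNA and 14 for the difference. In the comparison of RNA types, 2 were higher and 216 lower in TRAP than in Total RNA. Lower calls made up 30.6% of these loci and 22.98% of loci with an identifier, and their medians were -0.66 and -0.41 (camera p = 0.0121, and p = 0.0528 with an estimated correlation). Under median-ratio scaling 13 were higher and 75 lower. XLOC_012727 (chromosome 2, 37661343 to 37661473) was at 225 to 576 FPKM in the Total libraries and listed at 0 in all 4 TRAP libraries. It spans under 300 bp, and 78.7% of tested loci that short were at 0 in some library, against 2.32% of longer ones. A failed FPKM estimate is therefore not excluded for it. How far short loci add to the share of lower calls here was not tested.

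The count of 4830 loci past the threshold moved with single libraries. It became 463 without Total inoculated replicate 1, 465 without Total inoculated replicate 2 and 1733 without TRAP mock replicate 1. It was 2112 without Total mock replicate 2, 2274 without Total mock replicate 1 and 2575 without TRAP inoculated replicate 1. RPL18 gene Medtr1g083460 stayed past the threshold in 15 of 18 settings, with log2 differences from 3.24 to 4.60.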

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

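The count of splits in this part was chosen only after the result was seen. The cytosolic ribosomal protein list differed between the TRAP and the Total response to inoculation by a test of the difference itself (camera on the interaction, adjusted p = 0.0366), with 91 of 102 members higher in the TRAP response, a median difference of 0.18 and an adjusted p of 0.998 with an estimated correlation. The flavonoid biosynthesis list differed in the same test (adjusted p = 0.00863), with 52 of 75 members higher in the TRAP response, a median difference of 0.16 and an adjusted p of 0.998 with an estimated correlation.

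For the loci that differ between TRAP and Total RNA, a fit of 2 groups of 4 libraries called 7461 loci, and 1 of the 35 splits of the 8 libraries, the real one, gave as many. This count excludes chance only if libraries that share a replicate number are independent; splits that keep them paired are too few for a share under 0.05. The highest of the other splits gave 213 loci; it separates the libraries with replicate number 1 from those with number 2, and points to a structure of the samples that follows these numbers.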

How the results depend on the processing

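The setting without loci under 300 bp was chosen after seeing the data; it gave 7 loci for Total, 4 for TRAP, 0 for the interaction and 4859 for TRAP against Total RNA. Except where given here, the number of loci past the threshold stayed within 1.5 times its value in each comparison, under each pseudocount, filter, scaling, eBayes option and fold minimum tried. With no filter Total RNA had 5 loci higher and 1 lower, and 3 of the 8 were kept. The Total count became 5 with a pseudocount of 0.1, and the TRAP count 2 with a pseudocount of 5, 1 with no filter and 2 with a filter of 5 FPKM, where fewer loci are tested. With the spread from the 4 compared libraries alone both became 0. TRAP against Total RNA gave 2660 loci with the filter of 5 FPKM, 2928 with a log2 fold change of at least 1, 1789 with median-ratio size factors and 1653 with quantile normalization, which move the median of all loci to near 0. With 1 library left out, where the lone library of a group is assumed to vary like the others, the counts ran from 0 to 7 for Total, 1 to 6 for TRAP, 0 to 2 for the interaction and 463 to 5106 for TRAP against Total RNA; fewer libraries carry the spread in each.

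Replicate numbers are shared across groups, but the labels do not say what they share. Across loci, the differences between replicate 1 and 2 correlated at 0.53 between Total mock and Total inoculated, 0.67 between TRAP mock and TRAP inoculated, and 0.08 to 0.38 between Total and TRAP groups. With the replicate block the counts were 10 higher and 0 lower for Total, 7 and 2 (9) for TRAP, 0 for the interaction, and 590 and 6458 for TRAP against Total RNA; all 8 Total and 4 TRAP loci were kept. The TRAP loci added were Medtr6g022560 (adjusted p = 0.0410), Medtr3g031270 (0.0210) and Medtr1g096310 (0.0372), higher, and XLOC_051136 (0.0210) and Medtr8g031990 (0.0372), lower. List members past the threshold for TRAP against Total RNA became 17 for flavonoid, 39 for ethylene, 14 for cytokinin, 12 for gibberellin, and 33 for defence. They became 21 for cell cycle and histones, 69 for cell wall, 19 for photosynthesis and 64 for heat shock genes. Loci without an identifier in the TRAP response became 1 (2 with a pseudocount of 0.1). Camera also called nitrate and nitrogen lower in Total RNA (adjusted p = 0.00256) and in TRAP against Total RNA (0.00915), and photosynthesis lower for the interaction (0.0242). The cause was not tested.

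The members past the threshold under median-ratio scaling, then quantile normalization, are those for TRAP against Total RNA. Early nodulation had 1 and 1, signalling 2 and 2, late nodule genes 0 and 0, nodulins 9 and 6, and NCR and leghemoglobin 0 and 1. Ribosomal proteins had 1 and 10, translation factors 5 and 9, flavonoid 3 and 3, and ethylene 14 and 13. Cytokinin had 4 and 4, auxin 12 and 13, gibberellin 4 and 4, and peroxidases 10 and 15. Cell wall had 26 and 20, nitrate 6 and 2, vascular 2 and 2, RNA silencing 2 and 1, and heat shock 17 and 19. Hypothetical proteins had 247 and 209, and loci without an identifier 88 and 67. Photosynthesis had 17 under median-ratio scaling; reference genes had 1, and NF-Y, GRAS and ARF factors 7, under quantile normalization. Quantile normalization added camera calls. In Total RNA these were ribosomal proteins, higher (adjusted p = 0.0161), and nitrate, lower (0.0455). In TRAP RNA they were cell cycle and histones (0.0282) and translation factors (0.0466), both higher. For the interaction they were photosynthesis (0.0431) and early nodulation (0.0466), both lower. For TRAP against Total RNA they were nitrate (0.0107; 0.0140 under median-ratio scaling) and signalling (0.0491), both lower. Both scalings shift all loci, which moves calls of either direction. Hypothetical proteins had 1 in Total RNA with a pseudocount of 0.1 and 0 in TRAP RNA with quantile normalization. With an estimated inter-gene correlation the camera adjusted p was 0.320 and 0.926 for early nodulation genes in Total and TRAP RNA and 0.998 for the other 12 calls.

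Log2 differences that turned sign were near 0 or from loci that did not pass, and the cause was not tested. In TRAP against Total RNA, Medtr4g032660 gave 0.33 with median-ratio scaling, 0.13 with quantile normalization and -0.28 to 0.036 with 1 library left out. Medtr7g112880 gave 0.14 with median-ratio scaling. Medtr7g108805 gave -0.22 with quantile normalization and -0.33 to 0.38 with 1 library left out. The remaining ranges are with 1 library left out. Medtr6g070890 gave -0.93 to 0.025 in Total RNA. In TRAP RNA Medtr3g046320 gave -0.039 to 0.74, Medtr5g068780 -0.00489 to 0.94 and Medtr7g010930 -1.35 to 0.26. For the interaction Medtr1g061670 gave -0.12 to 0.76, Medtr3g046320 -0.083 to 0.69 and Medtr4g033170 -0.011 to 2.35. Named genes past the threshold kept their direction in every setting tried. Of their values, 61 of 149 in Total, 35 of 76 in TRAP and 116 of 695 in TRAP against Total RNA no longer passed. Of the values of named genes that did not pass in TRAP RNA, 8 of 445 passed. ENOD11 passed in 15 of 19 settings in Total (log2 difference 3.78 to 7.16) and 18 of 19 in TRAP RNA (4.13 to 7.20). Depth is unknown. The tests on simulated data, whose noise was independent between libraries, recovered 0% of 2-fold responses and 52% of 4-fold ones.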

Other observations

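All tests in this part were chosen after the results were seen. Besides the lists, 82 families of at least 20 tested loci that share a description were compared between TRAP and Total RNA. After 2 descriptions of TIR-NBS-LRR genes, the lowest medians in TRAP RNA were those of sugar porters (-1.08, 20 of 25 members lower), glycoside hydrolase family 1 proteins (-1.03, 15 of 29) and amino acid transporters (-1.01, 27 of 46). Under median-ratio scaling these medians were -0.67, -0.60 and -0.63, and the members lower fell to 5, 3 and 5. The highest medians, against -0.42 for all loci, were those of light-harvesting complex I proteins (0.63, with 1 of 21 members higher and 0 lower) and core histones (0.39, with 1 higher and 2 lower of 41). Plastocyanin-like proteins followed at 0.25 (3 higher and 3 lower of 20), lipid transfer proteins at 0.11 (3 and 3 of 40) and thioredoxins at 0.09 (2 and 0 of 20). Under median-ratio scaling these 5 medians ran from 0.49 to 1.08, and the balance of calls turned for some. Members higher and lower were then 6 and 0 for core histones, 6 and 0 for plastocyanin-like proteins and 5 and 1 for lipid transfer proteins. They were 4 and 0 for thioredoxins and stayed at 1 and 0 for light-harvesting complex I proteins. Camera called 26 families lower and 12 higher, and 0 with an estimated correlation. Across all 19726 loci the difference fell with the span of the locus (Spearman rho -0.27; -0.36 in replicate 1 and -0.06 in replicate 2) and rose with its level (0.34; 0.42 and 0.12). Loci under 10 FPKM had a median of -0.59 and those of 100 FPKM or more 0.21. The level is the mean of all 8 libraries, so TRAP values enter both it and the difference. Part of the trend with level can therefore be built in.

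Next to ENOD11 on chromosome 3, the early nodulin-12A gene Medtr3g415650, 4818 bp away, went from 0.0666 and 0 FPKM to 7.62 and 10.8 FPKM in Total RNA, and Medtr3g415580, 34523 bp away, from 0 in both mock libraries to 4.60 and 5.96 FPKM, while Medtr3g415610, 18160 bp away, did not exceed 0.0475 FPKM in any library. The Nod factor hydrolase gene NFH1 lies 3876 bp from Medtr4g117000, a member of its own hydrolase family, and went from 0.253 and 0.282 FPKM to 3.74 and 0.729 FPKM. Medtr5g011950, a lipid transfer protein gene 3380 bp from Medtr5g011960, was listed at 0 in mock and at 2.92 and 1.66 FPKM after inoculation. NFH1 and Medtr5g011950 lie below the level filter, and the other 2 rising neighbours did not pass over all genes. Whether induced loci lie in groups stays open: 3 of the 8 loci called in Total RNA had neighbours rising at an unadjusted p under 0.05 within 50 kb, 4 in all in a fit without the level filter, against a mean of 0.829 for random sets (permutation p = 0.0157), but the test was chosen on these same neighbours. Reads shared between neighbouring copies of a family were not tested and stay open.

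Medtr1g083460, an RPL18 gene, was higher in TRAP than in Total RNA by 4.01 ± 0.78 on the log2 scale. A difference in scale between the libraries is argued against as the cause, since the value was 4.48 after median-ratio rescaling. Enrichment of ribosomal protein transcripts as a class would need a list median far above that of all loci, and it was 0.43 above. A candidate explanation that stays open is that transcripts of the tagged construct are captured through the nascent tagged protein; no library without the tag was analysed here, so that was not tested, and the spread between replicates, 10.5 and 24.8 times, leaves the size of the enrichment uncertain.

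Medtr1g083710 rose in Total RNA and was listed at 0 in all 4 TRAP libraries. Loss of transcripts of this level in TRAP libraries is argued against, since 0.169% of 8275 loci of similar level in inoculated Total RNA (14 loci) were at 0 in both inoculated TRAP libraries. Among 22 such loci under 300 bp, 6 were at 0 in both, or 27.3%, and 78.7% of tested loci under 300 bp were at 0 in some library against 2.32% of longer ones. The 8275, 14, 22 and 6 loci each include Medtr1g083710 itself. The span of 221 bp therefore goes with an FPKM estimate that failed at a short locus. Exclusion of the transcript from ribosomes stays open beside it, as untested. The values of 0 in both Total mock libraries, on which the rise rests, could be failed estimates too.

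TIR-NBS-LRR disease resistance genes, receptors of the plant immune system, were low in TRAP RNA: 86 of 111 tested loci were lower and 0 higher, with a median of -1.24 and 110 negative. A difference in scale is argued against as the whole cause by a median of -0.98 after median-ratio rescaling, where 30 were lower and 0 higher. Of 10000 random lists matched on span and level, 0% had a median as low, and their lowest was -0.92. Their median of -0.68 lies below the -0.42 of all loci, so span and level carry part of the shift. Whether they carry all of it stays open. The lists drew loci singly, whereas members of a family can vary together, and the matched level includes the TRAP libraries. Sugar porters, amino acid transporters, glycoside hydrolase family 1 proteins and pectinesterases also had 0% of matched lists as low. So did the cytochrome P450 family and cytochrome P450 family 71 descriptions. A share of 0% is therefore not particular to TIR-NBS-LRR genes. Replicate 1 alone is argued against by a family median 0.57 below that of all loci in replicate 2 (-0.57; -1.18 in replicate 1). Low ribosome association of these transcripts is a hypothesis. Reads shared between paralogs and RNA quality were not tested, and camera's call on the 2 descriptions of this class is lost with an estimated correlation (p = 0.226 and p = 0.230). The low median was not particular to the TIR class. Among related descriptions, LRR and NB-ARC genes stood at -0.98 (17 of 30 lower) and NB-ARC genes at -0.95 (15 of 32). CC-NBS-LRR genes stood at -0.92 (18 of 28) and NBS-LRR type genes at -0.91 (14 of 22). Under median-ratio scaling the members lower fell to 6, 0, 4 and 2, and 1 CC-NBS-LRR gene was higher.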
